A study of Homo sapiens with 3 samples.

How the data were processed

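RNA was measured by sequencing in 3 human diffuse intrinsic pontine gliomas (DIPG), high-grade gliomas of childhood that arise in the pons. None of the 3 tumours had been treated, per the labels. The tissue of 2 tumours came from a biopsy and that of 1 tumour from surgery, per the labels, and this is the sole label that separates them. Total RNA was extracted from frozen tissue, ribosomal RNA was removed by an enzymatic depletion kit (KAPA HyperPrep with RiboErase) and the libraries were read on an Illumina NovaSeq, per the labels' protocols. No selection for poly(A) was named, so nuclear and non-polyadenylated RNA remain in such libraries.

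The deposited table holds estimated counts per gene, 1 column for each tumour, keyed by Entrez gene identifier. They were made by the authors with kallisto against GRCh38, per the submitters' processing notes. Kallisto assigns reads to transcripts by compatibility and shares ambiguous reads among them by expectation maximisation, so the counts of near-identical genes and of overlapping transcripts are estimates. The kallisto version, the transcript annotation, the strand setting and the way transcript estimates were summed to genes are not given in the sources used here. The deposited estimated counts were already whole numbers, so rounding them changed no value. They were not normalized, and the column totals differed. The number of columns left unused was 0.

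Of 26595 rows, 26517 (99.7%) were matched to a gene symbol through the RefSeq gene table of assembly GRCh38.p14, and coordinates are given on that build. The 78 unmatched rows held at most 0.0463% of the counts of a tumour. The genes XIST and TSIX and genes located solely on the Y chromosome were left out of every step, and 26493 rows were kept. Totals of the deposited estimated counts were 70694883 in biopsy tumour 1, 34427690 in biopsy tumour 2 and 29766229 in the surgical tumour. The limit that a count of 0 allows was set at 3 counts, equal to 0.0511, 0.0751 and 0.0978 CPM (counts scaled to a common library total) in the same order. Intervals of shares are 95% Wilson intervals, and the widest reached 0.0137 percentage points to either side. Ratios that rest on few counts carry 95% exact intervals. The reads carried no stated molecular identifiers, so intervals and limits cover counting error and nothing else.

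Levels are CPM on library sizes scaled by the trimmed mean of M values (TMM), with factors of 0.831, 1.16 and 1.03 for the tumours in the order above. Each mean has the standard deviation over the 3 tumours. Variation between tumours was counted as genes with a mean of at least 10 CPM whose highest tumour was over 4 times the lowest on log2(CPM + 1), with a pseudocount of 1. The surgical tumour was compared with the 2 biopsies by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) on genes that passed filterByExpr with a minimum count of 10, with Benjamini-Hochberg adjustment at 0.05 over 20489 genes. That design leaves 1 residual degree of freedom, and the lone surgical tumour was assumed to vary like the biopsies. The prior degrees of freedom of this fit were infinite, so the spread of each gene was replaced by a trend over genes. Its adjusted p and SE therefore do not measure how far a given gene varies between tumours. The same fit was run with each biopsy tumour set against the remaining pair. An exact permutation test of 1 tumour against 2 cannot give a p below 0.333, so none was run for single values.

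Gene lists were tested with camera on log2 CPM (prior count 2), first with a preset correlation between genes of 0.01 and then with a correlation estimated for each list, with Benjamini-Hochberg adjustment over 35 lists. With 1 residual degree of freedom the estimated correlation is itself poorly known. In that setting camera also takes its p from that 1 degree of freedom, so hardly any list could pass. The forebrain and midbrain list was lost there although its estimated correlation, -0.0111, was below the preset 0.01. A loss in that setting therefore does not measure correlation between genes. With the preset correlation camera takes its degrees of freedom from the number of genes. Its p in that setting compares a list with other genes and does not measure how far the list varies between tumours. The direction of each list was also tested with fry, which compares a list with no other genes. The lists covered oligodendrocyte precursors, astrocytes, oligodendrocytes, neurons in general, brainstem neurons, cerebellar neurons, myeloid cells, microglia, monocytes and macrophages, T and NK cells, B and plasma cells, neutrophils, endothelium, mural cells and fibroblasts, red blood cells, and ependyma with choroid plexus. Others covered mesenchymal glioma state, hypoxia, cell cycle, interferon response, antigen presentation, immune checkpoints, surface targets, anterior HOX genes, posterior HOX genes, forebrain and midbrain regulators, hindbrain regulators, glioma drivers, Polycomb repressive complex 2, BMP response, Notch, glutamate receptor and neuron-to-glioma signalling, immediate early genes, housekeeping genes and nuclear RNA. In bulk tissue they describe RNA of the mixture, not cell numbers.

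The design, the lists, the first set of other settings and the rule for named genes were fixed before the data were examined. For levels, the rule took up to 4 members of each list with the highest mean CPM, members at 0 where a list was mostly undetected, and the 10 genes of highest mean CPM. For the surgical tumour it took the 12 higher and the 12 lower genes with the smallest adjusted p among those past the threshold and outside the range of both biopsies, and up to 4 members of each list called by camera with the largest fold in its direction. For variation it took the 10 genes with the largest highest-to-lowest fold and a mean of at least 10 CPM. Genes whose level can reflect a common germline deletion or haplotype were never named. The complement component 4 genes were added to that exclusion after their values were seen. Any other gene named in the text was chosen after its values were seen. Some genes that met the rule are not named or drawn in the figures, and the counts of called genes and the list results still include them.

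The alternatives were DESeq2 size factors, total counts, the DESeq2 Wald test, limma-voom, no filter beyond 1 count, a filter of 1 CPM in all 3 tumours, removal of mitochondrial and ribosomal genes, other pseudocounts and minimum levels, and each tumour left out in turn. Added after the data were seen were protein-coding nuclear genes alone, an edgeR likelihood ratio test with the dispersion estimated over the 3 tumours as one group, libraries thinned to the smallest total, and an offset per library by loess (span 0.3) on the median transcript length and GC content of each gene in GENCODE annotation on GRCh38.

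The test was tried on simulated counts with 200 changed genes in 20113. It recovered 5% of genes changed 4-fold and 66% of those changed 16-fold, all with the right sign, with 3 false calls among 74. For the list test, 1 simulated list of 15 genes shifted by -2 on the log2 scale was called at a camera adjusted p of 6.21e-15, and 0 of the unshifted lists were called. Simulated genes varied independently of each other, so this trial cannot show how often camera calls lists of genes that move together. For the gene test, each simulated gene was given the trend spread that the fit assumes. It therefore cannot show how many false calls arise where genes vary more than the trend. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.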

Results

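The transcriptomes of 3 untreated diffuse intrinsic pontine gliomas were measured from frozen tissue by ribosomal-RNA-depleted total RNA sequencing. Biopsy tumours 1 and 2 and 1 surgical tumour were represented by 1 library each. The libraries held 70694883, 34427690 and 29766229 estimated counts in that order, and 19739, 19845 and 19238 genes had at least 10 counts. All 3 tumours shared 15809 genes at 1 CPM or more. The series names no contrast, so the levels common to the tumours and their spread come first, followed by the comparison of the surgical tumour with the 2 biopsies.

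Astrocyte and oligodendrocyte precursor genes were among the abundant messenger RNAs when averaged over the 3 tumours. GFAP, the intermediate filament of astrocytes, averaged 14042 ± 4592 CPM (SD, n = 3) and was the most abundant nuclear protein-coding gene. The other astrocyte genes CLU, AQP4 and GJA1 averaged 2751 ± 2109, 2422 ± 1322 and 1993 ± 1784 CPM. Among precursor genes, the extracellular matrix genes VCAN, TNR and BCAN stood at 1899.5 ± 1269, 1755 ± 1416 and 1216 ± 624 CPM, and the phosphatase gene PTPRZ1 at 1393 ± 410.1 CPM. Myelin genes varied widely, with MBP at 1339 ± 1285 CPM, CNP at 344 ± 238 and TF at 146 ± 83.1.

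Neuronal genes stood below these glial genes. SYT1, SNAP25, NEFM and NEFL averaged 45.5 ± 40.2, 32.9 ± 27.0, 29.2 ± 17.4 and 27.7 ± 24.9 CPM (SD, n = 3). Of brainstem neuron genes, TPH2, the serotonin synthesis enzyme of raphe neurons, reached 18.6 ± 5.47 CPM, while SLC6A4, GLRA1 and SLC6A2 stood at 1.66 ± 0.338, 0.516 ± 0.423 and 0.461 ± 0.427 CPM. The cerebellar neuron genes CA8, ZIC1, CALB1 and FAT2 averaged 16.5 ± 13.3, 15.7 ± 18.3, 10.7 ± 4.34 and 6.82 ± 10.7 CPM.

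Myeloid and microglia genes stood highest among the immune cell lists. CSF1R, LAPTM5, C1QC and C1QB averaged 116 ± 89.7, 97.3 ± 86.5, 69.8 ± 53.8 and 62.3 ± 42.9 CPM (SD, n = 3). The microglia genes CX3CR1, SALL1, P2RY12 and GPR34 stood at 110.1 ± 119.6, 81.8 ± 33.3, 80.8 ± 105 and 46.0 ± 58.4 CPM. Monocyte and macrophage genes were lower, with STAB1 at 29.9 ± 7.31, CD163 at 18.0 ± 20.005, CD14 at 11.3 ± 9.25 and MRC1 at 4.15 ± 4.36 CPM. Of T and NK cell genes, KLRD1 reached 47.8 ± 19.96 CPM, whereas CCL5, IL7R and the T cell receptor component CD3G stood at 4.998 ± 1.27, 4.63 ± 1.22 and 2.38 ± 0.411 CPM. B and plasma cell genes peaked at 1.71 ± 1.14 CPM for DERL3, ahead of MZB1 at 1.41 ± 0.735 and BANK1 at 0.438 ± 0.240. Neutrophil genes were led by CSF3R at 16.2 ± 5.99 CPM, FPR1 at 8.43 ± 7.94, CXCR2 at 1.16 ± 0.505 and CEACAM8 at 0.984 ± 0.589.

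Vessel genes were less abundant than glial genes. Endothelial FLT1, VWF, PECAM1 and MFSD2A averaged 30.8 ± 6.20, 28.2 ± 20.2, 23.2 ± 5.56 and 15.5 ± 4.44 CPM (SD, n = 3), and the mural cell genes PDGFRB, ABCC9, RGS5 and NOTCH3 69.6 ± 34.96, 54.0 ± 17.1, 46.9 ± 16.2 and 40.5 ± 15.1 CPM. Haemoglobin RNA, a measure of blood in the tissue, stood at 58.7 ± 61.9 CPM for HBA2, 42.1 ± 47.4 for HBB and 29.9 ± 31.6 for HBA1, and SLC4A1 at 1.395 ± 0.622. Ependymal and choroid plexus genes were led by the water channel AQP1 at 443 ± 353 CPM, the axonemal dynein DNAH9 at 42.2 ± 55.3, RSPH1 at 24.5 ± 16.3 and CIMAP3 at 23.2 ± 26.9.

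Growth factor receptor and cyclin genes led the glioma driver list. EGFR averaged 725 ± 559 CPM (SD, n = 3), CCND2 541 ± 254, PIK3R1 519 ± 192 and NF1 323 ± 14.0. Among genes of surface immunotherapy targets, NCAM1 stood at 761 ± 176 CPM, CSPG4 at 145 ± 108 and ST8SIA1, the synthase of the ganglioside GD3, at 139 ± 3.45. Checkpoint genes were led by CD47 at 189.6 ± 67.3 CPM, SIRPA at 107 ± 19.2, VSIR at 61.4 ± 2.61 and CD276 at 29.1 ± 4.72. Antigen presentation genes stood at 359.6 ± 193 CPM for B2M, 278 ± 182 for CD74, 104 ± 27.2 for TAPBP and 104 ± 72.9 for HLA-DRA. IFI44L, IFI6 and IFIT2 of the interferon response averaged 70.4 ± 34.1, 36.1 ± 11.5 and 35.5 ± 5.16 CPM.

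Polycomb genes averaged 215 ± 42.0 CPM for RBBP4, 71.1 ± 28.3 for EZH1, 68.0 ± 36.5 for RBBP7 and 61.3 ± 10.9 for JARID2 (SD, n = 3). Notch pathway genes were led by NOTCH2 at 473 ± 19.2 CPM, NOTCH1 at 261 ± 114, HEY1 at 78.7 ± 22.7 and HES6 at 55.5 ± 16.01. Targets of BMP signalling included ID4 at 514 ± 215 CPM, ID3 at 127 ± 96.9, SMAD9 at 89.0 ± 12.8 and ID2 at 73.8 ± 26.0. The neurotrophin receptor gene NTRK2 reached 2974 ± 1474 CPM, and the glutamate receptor genes GRIA4 and GRIA2 249 ± 224 and 178 ± 158, with NLGN3 at 122 ± 37.1. Cell cycle genes were led by MKI67 at 71.4 ± 65.6 CPM, TOP2A at 37.8 ± 27.7, TPX2 at 17.6 ± 14.0 and FOXM1 at 17.4 ± 14.6. Mesenchymal state genes stood at 638 ± 508 CPM for TNC, 402 ± 193 for VIM, 379 ± 106 for CD44 and 69.7 ± 20.4 for EMP1. Hypoxia-inducible NDRG1, PGK1, LDHA and ENO2 averaged 83.1 ± 24.2, 74.2 ± 27.3, 72.4 ± 38.6 and 54.1 ± 35.5 CPM. The immediate early genes EGR1, BTG2, JUN and FOS, which respond within minutes to stimulation or handling, stood at 175 ± 239, 115 ± 52.2, 95.002 ± 42.0 and 94.1 ± 133 CPM.

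Regional patterning genes were present at low levels. Posterior HOX genes were nearly silent, with 18 of 19 genes of groups 8 to 13 under 1 CPM in all 3 tumours. HOXA10, HOXB8, HOXC10, HOXC13, HOXD9, HOXD12 and HOXD13 had no count in any of them. HOXB13 was the exception at 3.20 ± 1.98 CPM (SD, n = 3), ahead of HOXC9 at 0.272 ± 0.471, HOXD10 at 0.153 ± 0.109 and HOXC8 at 0.0736 ± 0.106. Among anterior HOX genes, which pattern the hindbrain, HOXD3, HOXA3, HOXC4 and HOXD1 averaged 9.18 ± 8.23, 8.65 ± 14.8, 6.69 ± 4.59 and 6.68 ± 9.41 CPM. The hindbrain regulators IRX1, IRX2 and PAX3 stood at 37.8 ± 16.02, 29.8 ± 3.24 and 26.9 ± 42.2 CPM. The forebrain and midbrain regulators SIX3, OTX1, OTX2 and EN1 averaged 15.6 ± 25.9, 10.97 ± 18.6, 4.41 ± 7.59 and 3.26 ± 5.65 CPM.

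Nuclear and structural RNA was abundant, which goes with depletion of ribosomal RNA in place of poly(A) selection. MALAT1 averaged 27459.8 ± 7504 CPM (SD, n = 3), RN7SK 22996 ± 11831, RN7SL2 21545 ± 6513 and RN7SL1 9301 ± 4881. Mitochondrial MT-CO1, MT-ND4, MT-ND5, MT-CYB and MT-CO3 completed the 10 most abundant genes at 12465 ± 7249, 10129 ± 8791, 5823 ± 3893, 5692 ± 3944 and 5597 ± 4233 CPM. Mitochondrially encoded genes took 8.46% of counts in biopsy tumour 1, 3.38% in biopsy tumour 2 and 4.74% in the surgical tumour. Nuclear protein-coding genes took 81.6% ± 1.60 (SD, n = 3), and the 10 genes with most counts in each tumour 13.5% ± 1.76. Ribosomal protein genes and ribosomal RNA took 3.41%, 1.98% and 0.694% of counts in biopsy tumour 1, biopsy tumour 2 and the surgical tumour. The housekeeping genes ACTB, RPLP0 and GAPDH averaged 1873 ± 1125, 548 ± 326 and 514 ± 178 CPM.

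The widest ranges between the 3 tumours included genes of the oligodendrocyte lineage, GPR17, BCAS1 and MBP. Of 11787 genes with a mean of at least 10 CPM, 1371 (11.6%) differed over 4-fold between the highest and the lowest tumour on the log2(CPM + 1) scale. Also among the 10 largest ranges were neuronatin (NNAT), at 0.222, 1.98 and 116 CPM in biopsy tumour 1, biopsy tumour 2 and the surgical tumour, and TENM2, a synaptic adhesion gene, at 87.5, 67.4 and 0.130 CPM. GPR17, a receptor of committed precursors, and BCAS1, a gene of early myelinating oligodendrocytes, stood at 172, 55.1 and 1.27 CPM and at 545, 213 and 6.98 CPM. MBP stood at 2604, 1377 and 35.5 CPM, FERMT1 at 183, 157 and 1.70, PNMA6E at 0.0341, 0.0501 and 69.3, and IRS4, an insulin receptor substrate, at 0.102, 66.2 and 0. The microRNA host segments MIR3648-1 and MIR3648-2 each stood at 57.2, 1044 and 12.1 CPM; they lie in identical repeats beside ribosomal RNA genes, so the split between them is uncertain.

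The most distant of the 3 tumours was the surgical one for 709 of the 1371 variable genes, against 327 for biopsy tumour 1 and 335 for biopsy tumour 2. Between the biopsies 413 of the 11787 genes differed over 4-fold, against 832 and 753 between the surgical tumour and biopsy tumours 1 and 2. Spearman correlations across 20489 genes, which are not independent replicates, were 0.926 between the biopsies and 0.905 and 0.895 between the surgical tumour and biopsy tumours 1 and 2. The median absolute log2 difference ran the other way, at 0.546 between the biopsies against 0.482 and 0.496 between the surgical tumour and biopsy tumours 1 and 2. The number of variable genes without biopsy tumour 1, without biopsy tumour 2 and without the surgical tumour was 754, 853 and 426.

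The surgical tumour differed from the 2 biopsies in lineage and in regional identity genes. Camera with an estimated correlation had 1 degree of freedom and could hardly call any list, so a loss in that setting decides little. Camera with a preset correlation drew its degrees of freedom from the number of genes. However small, its p does not measure spread between tumours. By camera with a preset correlation, myelin, oligodendrocyte precursor, neuronal, microglial, cell cycle and anterior HOX genes were lower in it, and forebrain and midbrain regulators and genes of ciliated ependyma were higher. Each of these lists was lost with an estimated correlation (adjusted p = 0.738), no list passed fry (smallest adjusted p = 0.427), and the anterior HOX list rested mostly on biopsy tumour 2. SOX10, a regulator of the oligodendrocyte lineage, fell from 371 and 286 CPM in biopsy tumours 1 and 2 to 6.72 CPM, a log2 change of -5.61 (SE 1.28, edgeR quasi-likelihood adjusted p = 0.00122). OTX1, a regulator of forebrain and midbrain, rose from 0.324 and 0.150 to 32.4 CPM, a log2 change of 7.05 (SE 0.99, edgeR quasi-likelihood adjusted p = 2.32e-09). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 597 of 20489 genes, 262 higher and 335 lower in the surgical tumour, and 586 of the 597 lay outside both biopsies.

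The 12 leading genes that rose included the homeobox genes TLX2, ALX4 and OTX1. PNMA6E (Entrez 649238, chromosome X, 153395639 to 153414004), of a family with near-identical copies that make its count uncertain, had the smallest edgeR quasi-likelihood adjusted p, 1.14e-18. It stood at 2 counts in each biopsy and 2124 in the surgical tumour, a ratio of 1707 (95% interval 666 to 6270). TLX2 (Entrez 3196, chromosome 2, 74514450 to 74517148), a homeobox gene, was at 0 in both biopsies and 17.8 CPM in the surgical tumour, at least 237-fold higher against a limit of 3 counts per library. GJB2 (Entrez 2706, chromosome 13, 20187470 to 20192938), which encodes connexin 26, stood at 0.102, 0 and 30.3 CPM, a ratio of 498 (95% interval 228 to 1361). PAX2 (Entrez 5076, chromosome 10, 100735396 to 100829944), a regulator of the boundary between midbrain and hindbrain, stood at 0, 0.200 and 32.9 CPM, a ratio of 405 (95% interval 205 to 941).

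Other leading genes that rose were NNAT, GDF7, ALX4, MMP28, MAP3K19, OTX1 and NR2E1. GDF7, a BMP ligand of the roof plate, rose by 7.29 on the log2 scale (SE 0.98) to 38.4 CPM. NNAT rose by 6.74 (SE 0.86) to 116 CPM, the metalloprotease gene MMP28 by 6.37 (SE 0.88) to 59.9 CPM and the kinase gene MAP3K19 by 6.12 (SE 0.85) to 79.3 CPM. ALX4, a homeobox gene, stood at 19.9 CPM against 0.0511 and 0.0501, and NR2E1, a nuclear receptor of neural stem cells, at 28.9 CPM against 0.239 and 0.125. Their edgeR quasi-likelihood adjusted p ranged from 1.95e-11 for NNAT to 2.32e-09 for NR2E1.

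The 12 leading genes that fell included the myelin gene MAG, the neuronal genes INA and STMN2, and HOXD3. MAG (Entrez 4099, chromosome 19, 35292161 to 35313807), the myelin-associated glycoprotein, fell from 57.4 and 33.6 CPM to 0.0652 CPM, which is 2 counts, and the biopsy-to-surgical ratio was 732 (95% interval 203 to 6046). TENM2 (Entrez 57451, chromosome 5, 166979029 to 168264157) had a ratio of 609 (95% interval 238 to 2234) and CNTNAP4, a contactin-associated neuronal gene, of 795 (95% interval 143 to 31431) on 1 count in the surgical tumour. The chromatin remodeller gene CHD5 fell by 7.88 on the log2 scale (SE 1.27), the neuronal filament gene INA by 7.83 (SE 1.30) and the myelin cytoskeleton gene ERMN by 6.78 (SE 1.16). STMN2, a tubulin-binding gene of neurons, fell from 39.1 and 28.8 CPM to 0.228 CPM. HOXD3 and KLHL1 were at 0 in the surgical tumour, at least 141-fold and 152-fold lower. HAGLR, a long non-coding RNA of the HOXD cluster, stood at 39.9, 21.3 and 0.0652 CPM. H2AC18 was at 0 and at least 218-fold lower, but its count is uncertain because H2AC19 is nearly identical. IRS4 was at 0 and at least 339-fold lower than the biopsy mean, which rested on biopsy tumour 2: without it the difference on log2(CPM + 1) was -0.14. The edgeR quasi-likelihood adjusted p of these 12 genes ranged from 3.22e-09 for IRS4 to 2.17e-06 for ERMN.

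**Figure D1:**
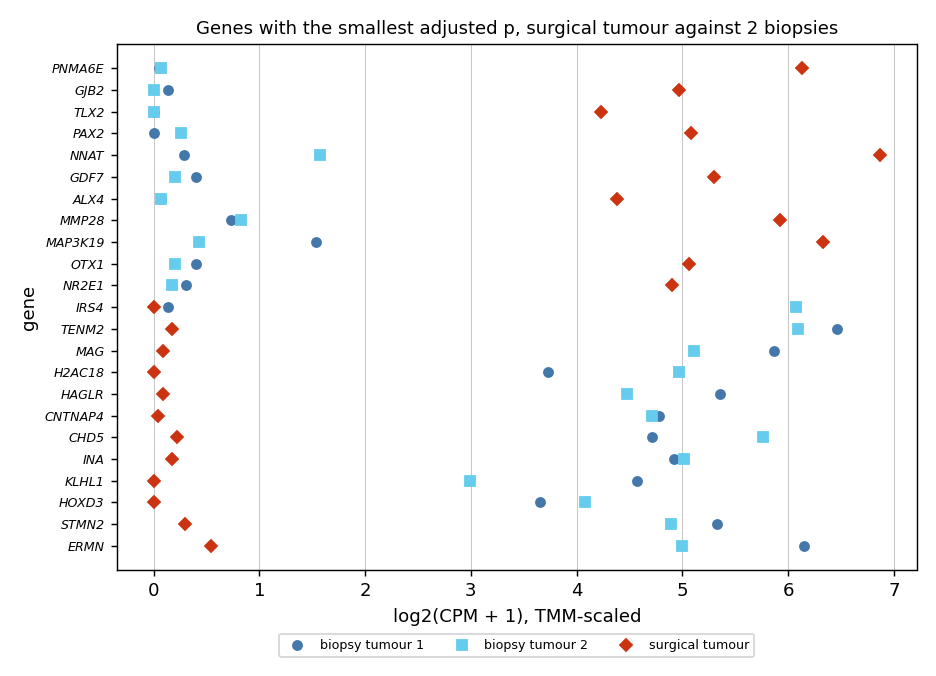
Level of leading higher and lower genes, those with the smallest adjusted p in the surgical tumour against the 2 biopsies. Each point is 1 tumour, the horizontal axis is log2(CPM + 1) with TMM scaling, and the surgical tumour lies outside both biopsies for every gene shown, from 116 CPM for NNAT to 0 for IRS4, H2AC18, KLHL1 and HOXD3.

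Genes of the oligodendrocyte lineage were mostly lower in the surgical tumour. Of 15 tested oligodendrocyte and myelin genes, 9 fell and 0 rose (10 fell when adjusted over the list alone), with a median log2 fold change of -4.02 (camera adjusted p = 8.29e-20, adjusted p = 0.738 with an estimated correlation). MAG and ERMN were joined by OPALIN, which fell by 6.18 (SE 1.88), and MBP, which fell by 5.81 (SE 1.74, edgeR quasi-likelihood adjusted p = 0.0333). On log2(CPM + 1), the oligodendrocyte median was -2.53 without biopsy tumour 1 and -3.77 without biopsy tumour 2. Of 16 oligodendrocyte precursor genes, 6 fell and 0 rose (10 fell when adjusted over the list alone), with a median of -2.78 (camera adjusted p = 3.38e-14, adjusted p = 0.738 with an estimated correlation). GPR17 fell by 6.48 (SE 1.17), OLIG1 by 4.32 (SE 1.20) and PDGFRA, the receptor that marks precursors and is often amplified in these gliomas, by 4.15 (SE 1.28, edgeR quasi-likelihood adjusted p = 0.0410) from 761 and 350 to 31.2 CPM.

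Neuronal and glutamate receptor genes were lower as well. Of 14 tested neuronal genes, 5 fell and 0 rose (9 fell when adjusted over the list alone), with a median of -2.60 (camera adjusted p = 2.72e-07, adjusted p = 0.738 with an estimated correlation). Beside STMN2, SYT1 fell by 5.66 (SE 1.08), NEFL by 3.98 (SE 0.99) and SNAP25 by 3.17 (SE 0.94, edgeR quasi-likelihood adjusted p = 0.0296). On log2(CPM + 1), the neuronal median was -2.51 without biopsy tumour 1 and -1.39 without biopsy tumour 2. Of 9 glutamate receptor and neuron-to-glioma signalling genes, GRIA4 alone fell, by 4.47 (SE 1.22), and 3 fell when adjusted over the list alone, with a median of -1.03 (camera adjusted p = 0.00177, adjusted p = 0.738 with an estimated correlation). GRIA2, GRIA3 and GRM5 stood at 22.95, 20.02 and 4.92 CPM in the surgical tumour, each below both biopsies without passing. Of 9 tested cerebellar neuron genes, FAT2, CBLN1 and CA8 fell and ZIC1, a regulator of dorsal neural tube and cerebellum, rose by 2.82 (SE 0.81), the same 3 and 1 when adjusted over the list alone. The median of that list was -2.71, or -1.64 with genes at 0 set to their limit (camera adjusted p = 0.0263, adjusted p = 0.738 with an estimated correlation). FAT2 was at 1.13, 19.2 and 0.130 CPM and CBLN1 at 11.6, 0.651 and 0.130 CPM, so that each difference rested mostly on 1 biopsy. On log2(CPM + 1), the cerebellar list median was -0.14 without biopsy tumour 1 and -0.60 without biopsy tumour 2.

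Cell cycle and microglial genes were lower in the surgical tumour. Of 18 cell cycle genes, 3 fell and 0 rose (5 fell when adjusted over the list alone), with a median of -1.95 (camera adjusted p = 1.89e-09, adjusted p = 0.738 with an estimated correlation). UBE2C fell by 4.23 (SE 1.32), MKI67 by 3.68 (SE 0.99, edgeR quasi-likelihood adjusted p = 0.0116) from 67.2 and 139 to 8.05 CPM, and TOP2A by 3.20 (SE 0.94), while CCNB2 stood at 3.84, 9.97 and 0.848 CPM without passing. Of 8 microglia genes, 3 fell and 0 rose (5 fell when adjusted over the list alone), with a median of -2.65 (camera adjusted p = 2.36e-06, adjusted p = 0.738 with an estimated correlation). P2RY12 fell by 4.88 (SE 1.07), CX3CR1 by 4.26 (SE 1.07) and TMEM119 by 3.26 (SE 0.96, edgeR quasi-likelihood adjusted p = 0.0302), and P2RY13 stood at 51.3, 7.14 and 3.78 CPM without passing. None of 12 pan-myeloid genes passed over all genes, 6 fell when adjusted over the list alone, and the median was -1.999 (camera adjusted p = 2.46e-06, adjusted p = 0.762 with an estimated correlation). TREM2, AIF1, CSF1R and LAPTM5 stood at 5.51, 5.31, 30.2 and 26.2 CPM in the surgical tumour against 47.5, 49.3, 209 and 194 in biopsy tumour 1 and 15.9, 10.2, 109.6 and 72.1 in biopsy tumour 2. Biopsy tumour 1 carried much of both differences: on log2(CPM + 1) the microglia median was -1.14 without biopsy tumour 1 and -3.05 without biopsy tumour 2, and the pan-myeloid median -1.27 and -2.27.

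In each of the macrophage, stromal and mesenchymal lists 1 gene rose, CD163, COL1A1 and CHI3L1 in that order. Of 9 tested monocyte and macrophage genes, the scavenger receptor gene CD163 rose by 2.63 (SE 0.80, edgeR quasi-likelihood adjusted p = 0.0367) to 40.9 CPM and 0 fell, and 3 rose when adjusted over the list alone. The median was 1.06 (camera adjusted p = 0.0178, adjusted p = 0.774 with an estimated correlation), and F13A1, MRC1 and LYZ stood at 6.03, 9.06 and 4.89 CPM without passing. Of 14 mural cell and fibroblast genes, the collagen gene COL1A1 rose by 4.05 (SE 0.85) to 36.3 CPM and 0 fell (2 rose when adjusted over the list alone), with a median of 1.01 (camera adjusted p = 0.000262, adjusted p = 0.738 with an estimated correlation). LUM, COL3A1 and KCNJ8 stood at 4.47, 13.8 and 16.9 CPM without passing. Of 13 mesenchymal state genes, CHI3L1 rose by 4.04 (SE 0.81, edgeR quasi-likelihood adjusted p = 0.000127) to 53.6 CPM and 0 fell (2 rose when adjusted over the list alone), with a median of 0.92 (camera adjusted p = 0.0125, adjusted p = 0.738 with an estimated correlation). TGFBI and TNC of that list stood at 12.1 and 1220.1 CPM without passing. On log2(CPM + 1), the monocyte and macrophage median was 0.886 without biopsy tumour 1 and 0.586 without biopsy tumour 2. In the same order the mural cell and fibroblast median was 0.732 and 1.09, and the mesenchymal median 1.19 and 0.782.

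Ciliated ependymal genes were mostly higher in the surgical tumour. Of 9 ependymal and choroid plexus genes, 4 rose and 0 fell, the same numbers as when adjusted over the list alone, with a median of 1.81 (camera adjusted p = 3.76e-06, adjusted p = 0.738 with an estimated correlation). FOXJ1, the master regulator of motile cilia, rose by 3.55 (SE 0.79, edgeR quasi-likelihood adjusted p = 0.000899) from 6.82 and 2.98 to 57.3 CPM. DNAH9 rose by 3.36 (SE 0.77), CFAP126 by 3.01 (SE 0.84) and CIMAP3 by 2.79 (SE 0.78). The choroid plexus genes TTR and KL stayed at or under 1.03 and 0.293 CPM in all 3 tumours.

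**Figure D2:**
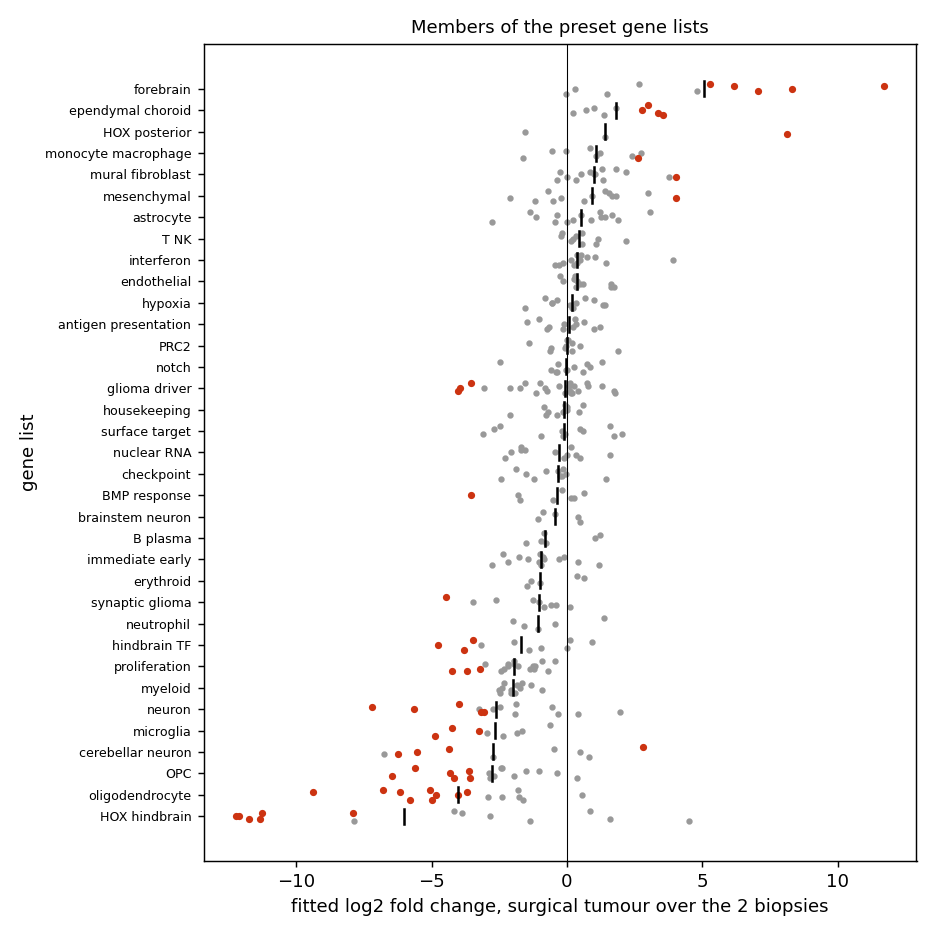
Log2 fold change of the surgical tumour against the 2 biopsies for the members of each gene list. Each point is 1 gene, red where the edgeR quasi-likelihood adjusted p is under 0.05, and the black bar is the median of the list, from -6.01 for anterior HOX genes to 5.06 for forebrain and midbrain regulators.

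Regional identity genes set the surgical tumour apart. Of 10 tested forebrain and midbrain regulators, 5 rose and 0 fell (6 rose when adjusted over the list alone), with a median of 5.06 (camera adjusted p = 2.90e-14, adjusted p = 0.738 with an estimated correlation). EN1 (Entrez 2019, chromosome 2, 118842171 to 118847648), a regulator of midbrain and anterior hindbrain, was at 0 in both biopsies and 9.78 CPM in the surgical tumour, at least 130.2-fold higher. On log2(CPM + 1), which shrinks folds near 0, the list median was 1.21 without biopsy tumour 1 and 1.18 without biopsy tumour 2. OTX2 rose from 0.0682 and 0 to 13.2 CPM, SIX3 from 0.614 and 0.626 to 45.5 CPM (edgeR quasi-likelihood adjusted p = 9.76e-09) and EN2 from 0.0682 and 0.0501 to 2.48 CPM.

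Of 14 tested anterior HOX genes, 6 fell and 0 rose over all genes, and 8 fell and 1 rose when adjusted over the list alone. Their median was -6.01, or -4.03 with genes at 0 set to their limit (camera adjusted p = 1.37e-07, adjusted p = 0.738 with an estimated correlation). HOXA2, HOXA3, HOXD1, HOXD3 and HOXD4 had no count in the surgical tumour, at least 76.6-fold, 133-fold, 102-fold, 141-fold and 72.6-fold lower, and HOXA4 stood at 0.0326 CPM. Both biopsies expressed HOXD3, at 11.6 and 15.9 CPM, and HOXD4, at 6.29 and 7.91 CPM, but they differed in HOXA genes: HOXA2, HOXA3 and HOXA4 stood at 14.9, 25.7 and 16.5 CPM in biopsy tumour 2 and at 0.0682, 0.205 and 0.358 in biopsy tumour 1. HOXD1 stood at 17.4 CPM in biopsy tumour 1 and 2.60 in biopsy tumour 2. On log2(CPM + 1), the list median was -1.79 without biopsy tumour 1 and -0.25 without biopsy tumour 2. Annotated HOXA3 spans HOXA4, HOXD3 overlaps HOXD4 and HAGLR overlaps HOXD1, so the split of estimated counts among them is uncertain.

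Of 10 hindbrain regulators, 3 fell and 0 rose (4 fell when adjusted over the list alone), with a median of -1.68 (camera adjusted p = 0.0173, adjusted p = 0.738 with an estimated correlation). Each rested on 1 biopsy: PAX3 stood at 1.53, 75.6 and 3.52 CPM, EGR2 at 42.3, 3.81 and 1.66, and NKX6-1 at 10.5, 0.200 and 0.196. EGR2 stood highest in biopsy tumour 1, as did the immediate early genes FOS and EGR1, so its fall need not reflect regional identity. GBX2, which sets the anterior hindbrain against the OTX2 domain, stood at 10.1, 3.03 and 0.717 CPM without passing. Of 3 tested posterior HOX genes, HOXC9 rose from 0 in both biopsies to 0.815 CPM, at least 10.8-fold, 1 gene as when adjusted over the list alone (camera adjusted p = 0.0904).

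**Figure D3:**
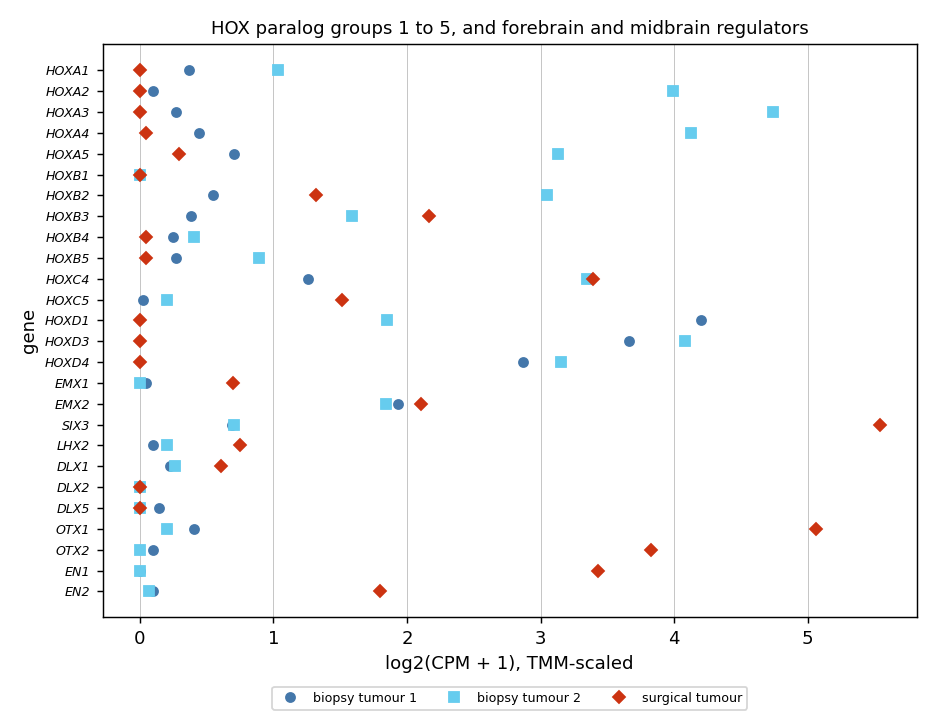
Levels of HOX genes of groups 1 to 5 and of forebrain and midbrain regulators in each tumour, on log2(CPM + 1) with TMM scaling. Each point is 1 tumour. OTX1, OTX2, EN1 and SIX3 stand highest in the surgical tumour, at 32.4, 13.2, 9.78 and 45.5 CPM, and HOXA2 and HOXA3 in biopsy tumour 2, at 14.9 and 25.7 CPM.

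Other lists were not called as lists by camera. Of 25 glioma driver genes, MYC fell by 3.94 (SE 0.99, edgeR quasi-likelihood adjusted p = 0.00502) from 117 and 43.3 to 5.22 CPM, the histone gene H3C2 by 4.02 (SE 1.02) and ID3 by 3.53 (SE 1.05), the same 3 when adjusted over the list alone (camera adjusted p = 0.140). EGFR stood at 323, 489 and 1363 CPM without passing. ID3 was also the single one of 8 BMP response genes to fall, over all genes and when adjusted over the list alone (camera adjusted p = 0.133). None of 12 surface target genes passed over all genes, although 3 fell when adjusted over the list alone (camera adjusted p = 0.865).

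In each of the following lists 0 genes passed, over all genes and when adjusted over the list alone. The camera adjusted p was 0.133 for astrocyte genes, 0.102 for endothelial, 0.142 for T and NK cell, 0.901 for B and plasma cell, 0.323 for neutrophil, 0.982 for red blood cell and 0.975 for brainstem neuron genes. It was 0.0550 for interferon response, 0.901 for antigen presentation, 0.158 for checkpoint, 0.770 for hypoxia, 0.217 for immediate early, 0.658 for housekeeping and 0.676 for nuclear RNA genes, and 0.894 and 0.901 for Polycomb and Notch genes. Astrocyte genes had a median of 0.52, with GFAP at 18651, 9468 and 14008 CPM. The Polycomb and Notch medians were -0.01 and -0.02 although camera placed both lists on the higher side, and antigen presentation genes had a median of 0.06 and a mean of -0.03.

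With 1 tumour of 1 person on the surgical side, a difference of procedure cannot be told apart from a difference between persons or between sites of sampling. The edgeR quasi-likelihood adjusted p and SE of a gene rest on a spread shared over genes, not on its own spread. The same edgeR quasi-likelihood test called 0 genes with either biopsy tumour set apart, at 664 and 937 genes with an unadjusted p under 0.05 against 1907 for the surgical tumour, but on unlike dispersion fits, with prior degrees of freedom of 4.003 and 6.37 against an infinite value. DESeq2 called 124 and 128 genes with either biopsy set apart, limma-voom 0 and 0, and camera 9 and 10 lists against 15, with 0 in each case with an estimated correlation. An edgeR likelihood ratio test with the dispersion taken over all 3 tumours called 0 for the surgical tumour (1047 at an unadjusted p under 0.05).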

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

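The likelihood ratio test over one group, the protein-coding restriction, the thinning and the length and GC offset were chosen after the results were seen. Against 597 genes called between the surgical tumour and the biopsies (262 higher, 335 lower, 43.9% higher), total counts called 357 (167 higher, 190 lower), limma-voom 384 (220 higher, 164 lower, 57.3% higher) and the DESeq2 Wald test 756 (258 higher, 498 lower, 34.1% higher). A filter of 1 CPM in all 3 tumours called 242 (100 higher, 142 lower); it tested 293 of the 597 genes and kept 238. With the dispersion estimated over the 3 tumours as one group, a likelihood ratio test called 0 genes, 0 higher and 0 lower, with 1047 at an unadjusted p under 0.05; this dispersion takes any difference between tumours as noise. The other settings called between 556 and 803 genes, 803 of them with the length and GC offset. Of the 597 genes, 585 were kept with DESeq2 size factors, 338 with total counts, 538 by DESeq2 and 361 by limma-voom. Of 239 values of named genes, 211 stayed past the threshold, 28 kept their direction without it, 24 of them in the likelihood ratio test, and 0 reversed. GJB2, PAX2 and IRS4 did not pass by DESeq2, at adjusted p of 0.136, 0.442 and 0.325, nor IRS4 by limma-voom, at 0.0972. With 1 biopsy left out no test remains. All 48 of 48 fold changes kept their direction, but the rule fixed this in advance. It took only genes that lay outside both biopsies on the same scale.

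Of the 15 lists called, 0 were called with an estimated correlation, 13 were kept with no filter and 11 of those still tested with 1 CPM in all 3 tumours. Cerebellar neuron genes were lost in both and turned to the higher side in the second (adjusted p = 0.399 and 0.936), and were lost with the length and GC offset (adjusted p = 0.0631). Hindbrain regulators were lost with no filter (adjusted p = 0.0685), and monocyte and macrophage genes with 1 CPM in all 3 tumours (adjusted p = 0.0851). Gained were T and NK cell and endothelial genes with no filter (adjusted p = 0.0432 for both), astrocyte and endothelial genes with 1 CPM in all 3 tumours (0.0440 and 0.0465) and interferon genes with protein-coding genes alone (0.0429). The count of 1371 variable genes (11.6% of those examined) was 2004 (11.5%) at a minimum of 1 CPM, 554 (12.3%) at a minimum of 50 CPM and 955 (8.10%) with a pseudocount of 5, and ranged from 426 to 853 with 1 tumour left out. Of 416 level values, 412 moved by less than 1 SD. No paired analysis was possible because the groups come from different persons and share 1 replicate number. Depth limited genes near 0.0978 CPM in the surgical tumour.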

Other observations

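The tests of chance splits, of mRNAs with a 5' terminal oligopyrimidine tract, of neighbouring neurons and of choroid plexus were chosen after their results were seen, and the cilia and cytokine genes named here after the leading genes were seen. Axonemal genes beyond the ependymal list were higher in the surgical tumour. All 20 of 20 motile cilia genes stood above both biopsies, although most did not pass edgeR's quasi-likelihood test. The share would be 33.3% if the 3 tumours were interchangeable, a figure that was not measured in these libraries. SPAG17 rose by 4.17 (SE 0.83, edgeR adjusted p = 9.77e-05) from 3.15 and 2.05 to 47.1 CPM, DNAI1 by 4.08 (SE 1.003), DRC1 by 3.77 (SE 0.85) and ARMC3 by 3.47 (SE 0.77). The median log2 fold change of the list was 2.15, and the rise of FOXJ1 may be part of a broader motile cilia programme. These genes are regulated together and were not tested with an estimated correlation, so their number adds little to what 1 tumour can show.

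Biopsy tumour 1 stood out in immediate early RNA and in some cytokine genes. FOS stood at 248 CPM against 14.7 in biopsy tumour 2 and 19.4 in the surgical tumour, EGR1 at 451 against 27.8 and 47.1, FOSB at 77.7 against 3.36 and 8.93, and DUSP1 at 70.5 against 6.96 and 19.1. With biopsy tumour 1 set against the other tumours, the immediate early list had a median of 1.42 (camera adjusted p = 1.80e-07, adjusted p = 0.725 with an estimated correlation). In the same split camera also called myeloid (adjusted p = 2.15e-07), microglia (1.33e-05), oligodendrocyte (2.11e-05), oligodendrocyte precursor (0.000828), nuclear RNA (0.000892) and housekeeping genes (0.0155) higher, and interferon (0.000828) and mural cell and fibroblast genes (0.0146) lower, each at 0.725 with an estimated correlation. The chemokine genes CCL3 and CCL4 stood at 48.3 and 29.9 CPM in biopsy tumour 1, against at most 0.359 and 0.626 in the other tumours. TNF and IL1B stood at 7.67 and 7.02 CPM against at most 0.301 and 1.10. The chemokine genes CCL2 and CXCL8 differed less, at 6.17 and 1.70 CPM against at most 3.46 and 0.815. With biopsy tumour 2 set against the other tumours, anterior HOX genes had a median of 2.09 (camera adjusted p = 6.94e-07, adjusted p = 0.986 with an estimated correlation), and PAX3, IRS4 and MET stood at 75.6, 66.2 and 44.6 CPM in it. Camera also called cell cycle (adjusted p = 0.000484), neuronal (0.0239) and B and plasma cell genes (0.0368) higher in that split. It called immediate early (0.00355), ependymal and choroid plexus (0.00705), monocyte and macrophage (0.0201), astrocyte (0.0239), forebrain and midbrain (0.0276) and nuclear RNA genes (0.0276) lower, each of these lists at 0.986 with an estimated correlation. Both splits set a biopsy against a pair that holds the surgical tumour.

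The surgical tumour was set apart by 597 called genes. Thinning all libraries to the smallest total kept 581 of them, and the length and GC offset kept 596, which argue against depth and against length or GC bias as the whole source. With protein-coding nuclear genes alone 523 of 535 were kept, so the calls did not depend on having structural and mitochondrial RNA in the fit. Both fits used TMM scaling, which already offsets a few abundant RNAs. The setting therefore cannot decide whether such RNA took counts. The length and GC offset used median annotated lengths, so it does not cover bias on the lengths expressed. Of the 3 possible splits of the tumours, 1 gave as many genes, the real one, and the highest of the others gave 0, although on prior degrees of freedom of 4.003 and 6.37 against an infinite value; camera called 9 and 10 lists in the others against 15, 0 in each with an estimated correlation, and with 3 splits no share under 0.05 can be reached. The procedure, the person and the site of sampling stay open and cannot be told apart, because 1 tumour stands on that side.

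Most ribosomal protein genes were lowest in the surgical tumour, but their summed level also differed between the 2 biopsies. Of 83 tested, 78 stood below both biopsies, the median log2 fold change was -2.13, and 0 passed edgeR's quasi-likelihood test; their summed level was 41029, 17013 and 6709 CPM in biopsy tumour 1, biopsy tumour 2 and the surgical tumour. Their transcripts are short, with a median annotated length of 671 nt against 1143 nt for protein-coding genes. They lay below genes matched on length, GC content and level by a median difference of -1.94. Its SE of 0.0561 came from resampling these genes, so it does not measure spread between tumours. The length used was the median over all annotated transcripts of a gene, which need not be the length expressed. The match therefore cannot decide whether short transcripts were under-represented. The 20 non-ribosomal mRNAs with a 5' terminal oligopyrimidine tract, such as EEF1A1 and EEF2, had a median of -1.48, and 19 stood below both biopsies. Their median level was 442 CPM in biopsy tumour 1, 196 in biopsy tumour 2 and 124 in the surgical tumour. The biopsies thus differed in this class as well. A candidate explanation is therefore a shared fall of this mRNA class, which lower growth signalling or tissue handling could bring and which these data do not separate.

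The forebrain and midbrain regulators of the surgical tumour could come from neighbouring tissue in the specimen. The neuronal list had a median of -2.60, with 11 members below both biopsies and 2 above. This argues against more neuronal RNA than in the biopsies. It cannot exclude a smaller share of neurons from another region, because 13 of 15 members still reached 1 CPM in the surgical tumour. Choroid plexus would bring its most abundant mRNA, TTR, which stood at 0.717 CPM in the surgical tumour and 1.03 in biopsy tumour 2, which argues against it. Glial or ependymal cells of a neighbouring region, and a tumour that arose from a more anterior origin, were not tested apart and stay open.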
